A study of Drosophila melanogaster with 2 samples.

How the data were processed

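The series covered ChIP-seq of Unc-4 fused to eGFP in whole embryos of Drosophila melanogaster aged 6 to 18 h, with 2 biological replicates in 1 group. Chromatin had been sonicated to a labelled size range of 200 to 800 bp. Per the descriptions the fusion protein was recovered with an anti-GFP antibody, whereas the antibody label names unc-4. The age was taken from the source name, because the age label held a value that does not read as this range. The sample descriptions name possible controls, which were not analysed here.

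The files used were 8 peak lists on assembly dm6: a thresholded and a ranked list for each replicate, and 2 thresholded and 2 ranked lists for both replicates together. All had been filtered or ordered by the authors by the irreproducible discovery rate (IDR). Per the deposited text descriptions, all lists derive from replicate alignments and 1 further file shared by all of them, whose role is not stated there; the same file is listed behind tracks named as fold change over control and signal p-value, which were not analysed here. The peak caller, the aligner and their versions are not given in the sources used here. Each deposited list gives the authors' signal value per peak, whose scale is not stated and which is comparable only within a list. The deposited thresholded lists also give a score from 0 to 1000, which tests on the files showed to follow the global IDR, and the -log10 of the caller's q value (neg_log10_p, as the authors' column order has it). The deposited ranked lists give the -log10 of the global IDR, a value of the false-discovery kind. The deposited lists hold 1 other quantity, the summit offset in bp from the start of the peak. The thresholded lists held ranked peaks at a global IDR of 0.01 or less, except that between 96 and 153 such peaks per list were absent from them, for a reason not given in the sources used here. In the whole-series ranked lists, 16 columns on the separate inputs to IDR were not used. In the pooled list 57.1% of peaks had a single width of 516 bp, and 2 summits lay outside their peak.

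Read depth is unknown, because peak lists hold no counts of reads. Precision was therefore stated only as 95% Wilson intervals of shares of peaks or genes and as the SD of random placements.

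Genes, transcripts and TSSs were taken from the Ensembl BDGP6.54 annotation, and sequence from the RefSeq Release 6 plus ISO1 MT assembly. Nuclear chromosomes were 2L, 2R, 3L, 3R, 4, X and Y. Peaks on the mitochondrial genome were reported apart. Other scaffolds were left out. Printed positions count from 1. Replicate signals of a named peak are the highest among the overlapping peaks of that replicate's ranked list. Of the listed gene names, 1 list member was not analysed here.

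The pooled thresholded list was the main list, and the replicate and conservative lists were analysed beside it. Replicate overlap was the share of peaks overlapped by at least 1 bp, against 10000 random placements of the other replicate's peaks within their chromosomes (one-sided). Summits were assigned to promoter (within 1 kb of a TSS), 5' UTR, 3' UTR, coding exon, noncoding exon, intron or intergenic sequence, in that order, and compared with 10000 random placements (two-sided). Peaks per Mb on the X and on 2L, 2R, 3L and 3R were compared with an exact binomial test by sequence length. For each of 16 gene lists, the share of members with a summit in the gene or within 5 kb of either end was compared with 10000 random lists of coding genes matched on deciles of that window's length (two-sided); the p from such lists is called a permutation p, since membership was drawn anew among coding genes. The lists were the Unc-4 locus, motor neuron transcription factors, other neuronal transcription factors, Hox genes and cofactors, neuroblast and temporal factors, neurotransmitter synthesis and transport, pan-neuronal differentiation, axon guidance and synaptic adhesion, Notch pathway, glia, muscle, gut and fat body, trachea, ribosomal proteins, proteasome, and odorant and gustatory receptors. Six-mers on either strand were counted within 50 bp of each summit and in a window of the same 101 bp width centred 500 bp away on a randomly drawn side, and compared with exact McNemar tests over 2080 six-mers; TAATTA, TAATNNNATTA, GAGAGA, CAGGTA and CACGTG were named in advance and adjusted among themselves. Signal of promoter and other peaks was compared with a permutation test of 100000 resamples. Families of tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The smallest p that placements or random lists can give is 0.0001, and that of the permutations 1e-05.

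Tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took unc-4 and OdsH, the genes nearest to the 20 pooled peaks of highest signal, the 10 coding genes with the most summits, up to 4 members per list with the highest peak signal, up to 2 members per list without a peak in list order, and the 10 six-mers with the largest excess among those that passed. Not every gene taken by the rule is named in the text. Because the 20 strongest peaks were all mitochondrial, the 20 strongest nuclear peaks were described as well, chosen after their values had been seen. Genes around the Unc-4 locus and genes with the TSS nearest to a list member's peak were likewise named after their values had been seen.

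Alternatives changed 1 choice at a time: the conservative list, the 500 peaks of highest signal, each replicate alone, promoters within 250 bp or 2 kb, gene windows of 1 kb around a TSS or the gene of the nearest TSS, Fisher's exact test without matching, motif windows of 100 bp either side, flanks 1000 bp away, peaks more than 1 kb from a TSS, 50% reciprocal overlap, summits within 100 bp, the 500 strongest peaks of each replicate, and random placement near TSSs. The 500 nuclear peaks of highest signal were added after the data had been seen. No paired analysis was possible because there was 1 group.

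The tests were checked on simulated data. A six-mer planted in 200 of 4899 random windows was recovered at its planted gain of 3.88 percentage points, which checks the counting alone. In random windows 0 six-mers were called. Those windows were drawn across the chromosomes and not at promoters, so this does not give the rate of calls for promoter peaks. Of 200 random gene lists, 2.5% had a p under 0.05. When 60.0% of one list's peaks were copied into another, 61.4% were found, and random summits gave a promoter share of 23.9% (p = 0.717, permutation of positions). Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.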

Results

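Chromatin immunoprecipitation sequencing (ChIP-seq) measured where Unc-4, a homeodomain transcription factor known from neurons, lay on the genome of whole Drosophila melanogaster embryos aged 6 to 18 h. Unc-4 was expressed as a fusion to eGFP and recovered with an anti-GFP antibody. There was 1 group with 2 biological replicates, so the comparisons were replicate 1 against replicate 2 and the peaks against the rest of the genome. The pooled list of both replicates, the main list, held 4921 peaks, of which 4899 were nuclear and 22 mitochondrial. Some of these peaks overlap: the 4921 make up 4741 distinct intervals, or 4041 regions once overlapping ones are merged. Each peak was nevertheless counted and tested separately. A more conservative pooled list held 4496 peaks, replicate 1 alone 3480 and replicate 2 alone 2979. The read depth of either library was not given in the sources used here and is therefore unknown. The median nuclear signal was 107 in the pooled list, 116 in replicate 1 and 63.4 in replicate 2. Signal values are the authors' and can be compared only within a list. Peaks are not replicates, so p-values describe these libraries alone, and all intervals cover counting error only.

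The gene encoding the tagged factor held no peak of its own. Neither unc-4 (FBgn0024184, X:17768569-17778708, dm6) nor its neighbour OdsH (FBgn0026058, X:17791010-17814011), a homeobox gene known for hybrid male sterility, had a summit in the gene or within 5 kb in any of the 4 thresholded lists. The nearest pooled summit to unc-4 lay 25829 bp away in an intron of raskol, a Ras GTPase-activating protein gene, and the nearest to OdsH lay 13583 bp away at the promoter of Socs16D. Peaks at those flanking promoters had pooled signals of 912 at raskol and 668 at Socs16D. With a peak at 0 of 2 members, this list did not differ from random lists of matched length, in which 65.9% ± 33.1 (SD) of members had a peak (adjusted p = 0.183, two-sided permutation of lists). A list of 2 genes gives such a test little reach.

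**Figure D1:**
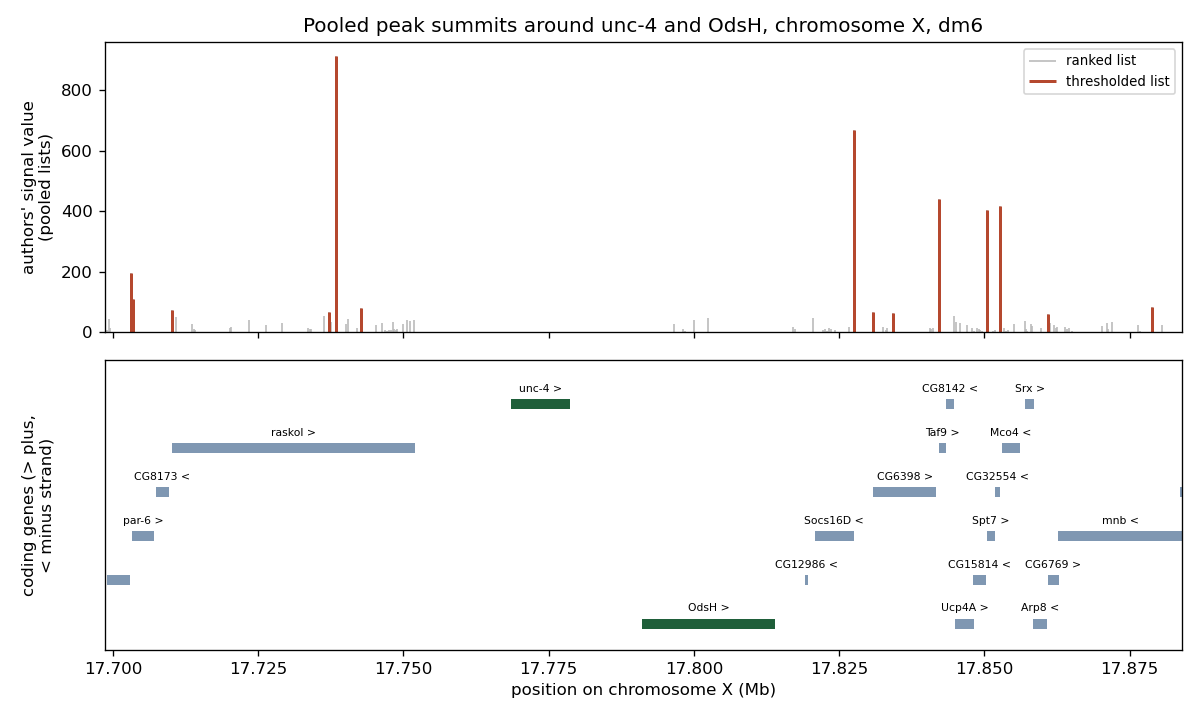
Pooled peak summits on chromosome X around unc-4 and OdsH, with the position in Mb on the x axis and the authors' signal value on the y axis, above the coding genes of the region. The 14 thresholded summits (red) all lie outside the unc-4 and OdsH genes, while summits of the ranked list (grey) are present in OdsH at low signal.

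The replicates shared most of their peaks. Of the 3457 nuclear peaks of replicate 1, 2628 (76.0%, 95% Wilson interval 74.6 to 77.4) overlapped a peak of replicate 2 by at least 1 bp. Of the 2960 of replicate 2, 2453 (82.9%, 81.5 to 84.2) overlapped a peak of replicate 1. Random placements of the peaks within their chromosomes gave 1.71% ± 0.24 (SD), and no placement reached the observed overlap (p = 0.0001, one-sided permutation of positions, the smallest that 10000 placements can give). Random placement near TSSs, at the observed share of promoter peaks, gave 9.06% ± 0.52 (SD) and did not reach it either (p = 0.0001, permutation of positions). Those placements took any annotated TSS and any position within 1 kb of it. By contrast, 68.5% of replicate 2 summits lay within 100 bp of a TSS. The placements therefore cannot tell whether the overlap goes beyond both libraries marking a common set of promoters. Signal was compared across 2230 pairs of peaks whose summits lay within 100 bp, each peak of replicate 2 used at most once. These pairs are peaks and not independent replicates, and they leave out shared peaks with summits further apart. Across them, signal had a Spearman coefficient of 0.865 and a Pearson coefficient of 0.842 on the log2 scale. The median gap between summits was 20 bp, which the pairing limits to at most 100 bp. The share fell to 55.8% of replicate 1 and 61.2% of replicate 2 when 50% reciprocal overlap was required.

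Peaks found in 1 replicate alone differed in sequence from the shared ones. The six-mer TATCGA lay within 50 bp of the summit in 47.6% of the shared peaks of replicate 1 and in 22.7% of its 829 unshared peaks, and in 49.6% of the shared peaks of replicate 2 and 9.27% of its 507 unshared peaks. GAGAGA, a sequence bound by GAGA factor and Pipsqueak, went the other way, with 3.92% against 7.36% in replicate 1 and 3.91% against 14.8% in replicate 2. The differences in TATCGA (adjusted p = 3.29e-38 and 1.26e-71, odds ratios 3.10 and 9.62) and GAGAGA (adjusted p = 0.000144 and 6.19e-17, odds ratios 0.514 and 0.235) passed two-sided Fisher's exact tests. Those in TAATTA, the core sequence of many homeodomain sites, did not (adjusted p = 0.333 and 0.224 in the same exact tests, odds ratios 0.859 and 1.40). The unshared peaks were also weaker, with a median signal of 62.6 against 161 in replicate 1 and 38.4 against 73.6 in replicate 2, and fewer were at promoters (89.0% against 96.9%, adjusted p = 1.33e-16, and 87.6% against 96.8%, adjusted p = 9.38e-15, in the same exact tests). The comparison of sequences was not matched on signal. These tests were chosen after the values had been seen. Of the unshared peaks, 94.7% in replicate 1 and 85.2% in replicate 2 overlapped the other replicate's ranked list of peaks before thresholding. Those ranked lists were long and unequal, with 45920 nuclear peaks in replicate 2 and 21280 in replicate 1. No random share was computed for them, so these figures do not measure agreement.

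Peaks lay almost entirely at the start of genes. Of the 4899 nuclear summits, 4526 (92.4%, 91.6 to 93.1) were within 1 kb of a transcription start site (TSS), against 23.7% ± 0.62 (SD) of random placements, 3.90 times as many. Introns held 223 summits (4.55% against 36.2%), intergenic sequence 104 (2.12% against 25.1%), 3' UTRs 19 (0.388% against 4.22%) and coding exons 14 (0.286% against 9.94%). The summit was typically just upstream of the TSS: the median position was -32 bp, 61.1% of summits were within 100 bp and 65.8% were upstream. Promoters held 3285 of the 3457 nuclear summits of replicate 1 and 2818 of the 2960 of replicate 2 (95.2%). The smaller classes moved more with the library: introns held 2.89% in replicate 1 and 2.57% in replicate 2, intergenic sequence 1.42% and 1.66%, coding exons 0.145% and 0.135%, 5' UTRs 0.116% and 0.0676%, and noncoding exons 0.116% and 0.0338%. Promoters, introns, intergenic sequence, 3' UTRs and coding exons each had a pooled adjusted p of 0.00014 against random placement (two-sided permutation of positions). Adjustment was over 7 classes. Before it, each of these p was 0.0001 (same permutation), the smallest the placements can give. The 6 summits in 5' UTRs (0.122% against 0.449%, adjusted permutation p = 0.000817) and 7 in noncoding exons (0.143% against 0.455%, adjusted permutation p = 0.0018) were also fewer than in random placements.

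**Figure D2:**
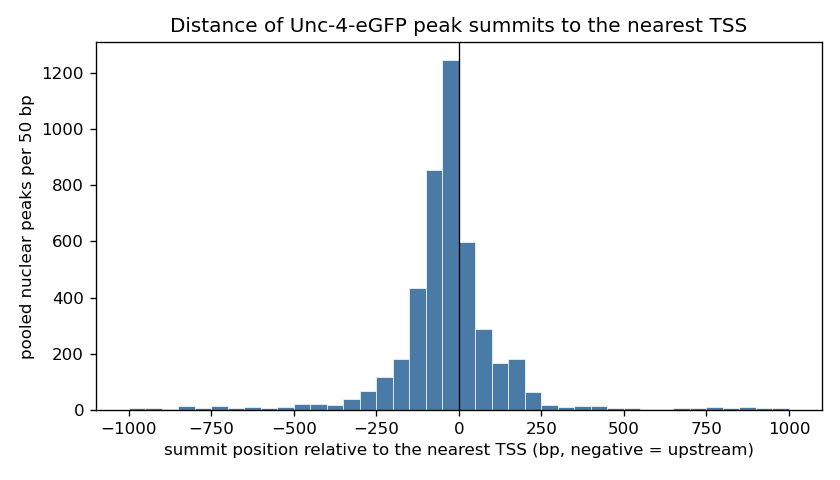
Number of pooled nuclear peaks (y axis, per 50 bp) by the position of the summit relative to the nearest TSS (x axis, bp, negative is upstream). The summits cluster just upstream of the TSS, with a median of -32 bp.

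The X and the major autosome arms did not differ detectably in peak density. The X held 910 peaks, 38.8 per Mb, and the major autosome arms 3978, 36.5 per Mb, a ratio of 1.06 that did not pass the test (p = 0.112, two-sided exact binomial test). Density was 42.5 peaks per Mb on 2R, 35.4 on 2L, 35.1 on 3R and 33.8 on 3L, while chromosome 4 had 8.26 (11 peaks) and Y held 0 peaks. On chromosome 4 there were 17 peaks (12.8 per Mb) in replicate 1 and 7 (5.26 per Mb) in replicate 2. The X ratio was 1.14 in replicate 1 (p = 0.00192, two-sided exact binomial test) and 1.02 in replicate 2 (p = 0.665). The difference between the replicates did not pass Fisher's exact test (odds ratio 1.12, p = 0.0786, two-sided).

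The strongest peaks of the pooled list were on the mitochondrial genome. All 20 of highest signal lay there, with nearest genes that included mt:tRNA:His-GTG (signal 35639), mt:ND5 (22611), mt:Cyt-b (21925), mt:tRNA:Lys-CTT (21772), mt:CoI (20814), mt:tRNA:Val-TAC (17345), mt:ND1 (13895), mt:CoIII (13597) and mt:ND2 (9637), which encode transfer RNAs and respiratory chain subunits. The highest of these signals was 22.3 times the highest nuclear one, and 21.1 and 22.0 times in replicates 1 and 2. Peaks covered 59.2% of the 19524 bp of the mitochondrial genome and 1.40% of the nuclear chromosomes. The mitochondrial peaks took no part in the other comparisons.

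Among nuclear peaks, the 20 of highest signal were all at promoters. The nuclear peaks named here were chosen after their values had been seen. The highest signal, 1598, was at the promoter of mtSSB (FBgn0010438, summit at -43 bp, peak at 3R:16205052-16205643), which encodes the mitochondrial single-stranded DNA-binding protein. It was followed by Rpn6, a proteasome lid subunit gene (1506, 2R:14752077-14752654), RhoGAP93B (1438), Creld (1308), Sry-alpha (1279), Nrg, which encodes the cell adhesion protein Neuroglian (1269), CG4502 (1238), Pym (1230), CG11857 (1225) and RpL32, a ribosomal protein gene (1162). All 20 were present in both replicates and in the conservative list, with a summit at most 149 bp from a TSS. Promoter peaks as a class were stronger than the rest, with a median signal of 114.7 over 4526 peaks against 71.2 over 373, a ratio of 1.61 (p = 1e-05, two-sided permutation test, the smallest that 100000 resamples can give).

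Several genes collected many summits in the gene or within 5 kb. These counts were not adjusted for gene length, and longer genes have wider windows. Ptp61F spans 132765 bp, EcR 81215 bp, SNF4Agamma 73531 bp and psq 59393 bp, but velo 8327 bp and EMC4 1069 bp. EcR, which encodes the ecdysone receptor, had 12, and psq, which encodes the GAGAGA-binding protein Pipsqueak, had 11. SNF4Agamma, a subunit gene of AMP-activated protein kinase, had 10, as did velo. Ptp61F, a tyrosine phosphatase gene, and nocte had 9 each, while Arf1, CG33170, EMC4 and Hakai had 8 each. Arf1, CG33170 and EMC4 lie side by side on 3L and had the same highest peak (signal 231). Replicates 1 and 2 alone gave 5 and 5 summits at EcR, 4 and 5 at psq, 5 and 5 at SNF4Agamma and 3 and 1 at velo. They gave 8 and 3 at Ptp61F, 5 and 2 at nocte, 6 and 2 at Hakai, and 4 and 6 at Arf1, CG33170 and EMC4.

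Proteasome and ribosomal protein genes held peaks more often than random lists. Of the 32 proteasome genes analysed, 30 (93.8%, 79.9 to 98.3) had a summit in the gene or within 5 kb, against 54.9% ± 8.72 (SD) in random lists (adjusted permutation p = 0.0004). Here and for the lists that follow, the value in parentheses after a gene is the highest pooled signal among its peaks, and a value in bp is that summit's position relative to the gene's own TSS. The highest signals were at Rpn6 (1506, summit at -99 bp from the TSS), Prosalpha7 (1159, -44 bp), Rpn10 (680) and Rpn2 (657, -79 bp). Rpn7 and Rpn8 were the 2 members without a peak. Ribosomal protein genes had peaks in 70 of 85 (82.4%, 72.9 to 89.0) against 52.2% ± 5.22 (adjusted permutation p = 0.0004), with RpL32 (1162), RpS2 (980), RpLP1 (925) and RpS13 (826) at the top and RpL10 and RpL10Aa among the members without. Of these 4, only the RpL32 peak was nearest to the gene's own TSS. Within 1 kb of a TSS, 27 of 32 proteasome and 54 of 85 ribosomal protein genes held a summit. The tests drew 10000 random lists matched on the length of the gene window, were two-sided and were adjusted over the 16 lists, all fixed in advance; the smallest adjusted p they gave was 0.0004. Among the 500 peaks of highest signal, of which 479 were nuclear and tested, the proteasome list no longer passed (9.69 percentage points above random lists, adjusted permutation p = 0.321). Over all its alternatives adjusted p ranged from 3.51e-05 (Fisher's exact test without matching) to 0.392 (permutation of lists, 500 nuclear peaks of highest signal).

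Odorant and gustatory receptor genes, which act in sensory neurons, held peaks less often than random lists. Only 17 of 119 (14.3%, 9.11 to 21.7) had a summit in the gene or within 5 kb against 56.9% ± 4.50 (SD) in random lists (adjusted permutation p = 0.0004), and only 2 of 119 had one within 1 kb of a TSS. The peaks with the highest signals near Gr59f (904), Or9a (617), Or43b (362) and Gr22f (346) were closest to the TSS of another gene, respectively wmd, Neb-cGP, Cul1 and CG17712. Gr10a and Gr10b were among the 102 members without a peak.

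Genes of 4 neuronal lists held peaks less often than random lists. Other neuronal transcription factors had peaks in 7 of 28 (25% against 64.1% ± 9.03 SD, adjusted permutation p = 0.0004), with pdm3 (103), unpg (102) and Ptx1 (79.9) among the highest and en and ap without a peak. Neuroblast and temporal factors had 4 of 19 (21.1% against 61.0% ± 11.1, adjusted permutation p = 0.00096): brat (437, summit at -112 bp), pros (352), insc (75.3) and grh (64.9), with hb and Kr without a peak. Neurotransmitter synthesis and transport genes had 6 of 16 (37.5% against 67.6% ± 11.6, adjusted permutation p = 0.0384), with the monoamine transporter gene Vmat (297), Ddc (291), Gad1 (143) and Hdc (103) highest and ChAT and VAChT, the cholinergic pair, without. Motor neuron transcription factors had 2 of 9 (22.2% against 62.1% ± 16.2, adjusted permutation p = 0.0466), zfh1 (205) and tup (75.9), while exex and Lim3 had none. The motor neuron list passed in neither replicate alone (adjusted p = 0.172 in replicate 1 and 0.0904 in replicate 2, permutation of lists), and the neuroblast list passed in replicate 1 (adjusted p = 0.00512) but not in replicate 2 (adjusted p = 0.0523); the difference between replicates was not tested. Of the members named with a peak, only pdm3, unpg, Ptx1 and brat had their strongest peak closest to their own TSS. The strongest peaks near pros, Vmat, Ddc, Gad1, Hdc and tup were at promoters closest to another gene, respectively Irbp, mip120, CG10561, wit, Csgalnact and CG10602. The peak at Ptx1 was in the thresholded list of replicate 2 and not of replicate 1, and the peaks near insc likewise. Those near tup and Hdc were in that of replicate 1 and not of replicate 2. When each summit was given only to the gene of its nearest TSS, none of these 4 lists passed (adjusted p from 0.127 to 0.321, permutation of lists). The gene window also counts summits at neighbouring genes. Random lists were matched on the length of that window and not on the number of TSSs within it. Counting only summits within 1 kb of a TSS, the neuroblast list did not pass (-23.6 percentage points, adjusted permutation p = 0.0798), whereas the other lists of this paragraph did. The neurotransmitter list also lost its call with Fisher's exact test without matching (-19.7 percentage points against -30.1, adjusted p = 0.302), as did the motor neuron list (-34.9, adjusted exact p = 0.117), and none of the 4 lists passed among the 500 strongest peaks. Over all alternatives, adjusted p ranged from 0.0131 to 0.506 for motor neuron, from 0.00512 to 0.392 for neuroblast, from 0.0004 to 0.252 for other neuronal factors and from 0.006 to 0.392 for neurotransmitter genes.

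Pan-neuronal, axonal, Notch and Hox genes did not differ detectably from random lists. Pan-neuronal differentiation genes had peaks in 7 of 16 (43.8% against 64.5% ± 11.9 SD, adjusted permutation p = 0.183), with the synaptic vesicle genes Syt1 (406) and nSyb (230) and the RNA-binding protein genes Rbp9 (182) and elav (102) highest, and Syx1A and Snap25 without. This list passed with replicate 1 on its own, with a difference from random lists of -29.2 percentage points (adjusted permutation p = 0.0494). It also passed in the conservative list (-30.4, adjusted permutation p = 0.0302) and for summits within 1 kb of a TSS (-29.6, adjusted permutation p = 0.0437). It passed in no other alternative, and adjusted p over all of them ranged from 0.0302 to 0.458. Axon guidance and synaptic adhesion genes had 15 of 26 (57.7% against 63.2% ± 9.50, adjusted permutation p = 0.786). Among them the promoters of the guidance receptor genes fra (645, summit at -147 bp) and robo1 (416, -58 bp) held peaks, those near Ten-m (339) and Lar (331) were closest to other genes, and robo2 and robo3 had none. The Notch pathway had 6 of 15 (40.0% against 54.3% ± 12.6, adjusted permutation p = 0.388), with neur (469), Su(H) (290, -7 bp), and E(spl)m7-HLH and E(spl)m8-HLH (251 for a peak they share, nearest to gro), and with numb and spdo without. Hox genes and cofactors had 4 of 10 (40.0% against 63.5% ± 15.0, adjusted permutation p = 0.26): Ubx (213), exd (195, 3 bp from its TSS), lab (68.4) and pb (67.1), with Dfd and Scr without. Within 1 kb of a TSS, 1 of 10 held a summit (10% against 41.3%, adjusted permutation p = 0.0798). The peaks of lab and pb were in neither replicate's thresholded list. The strongest peaks near Syt1, nSyb, Rbp9, neur, Ubx and pb were closest to the TSS of another gene, respectively Taf10b, Bgb, Ts, hyx, CG14907 and Ccp84Aa.

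Lists of other tissues did not pass the test either, but they are small, and their difference from the neuronal lists was not tested. Glial genes had peaks in 8 of 12 (66.7% against 66.6% ± 13.5 SD, adjusted permutation p = 1), with loco (575, summit at -38 bp), wrapper (558), moody (390) and gcm2 (194) highest. Gs2 and Eaat1 had no pooled peak but 2 and 1 in the conservative list. Muscle genes had 6 of 14 (42.9% against 64.6% ± 12.7, adjusted permutation p = 0.183), among them tin (446), Mef2, a regulator of myogenesis (361, -83 bp), up (222) and wupA (114.6), while bin and bap had none. Gut and fat body regulators had 5 of 10 (50% against 66.4% ± 14.9, adjusted permutation p = 0.388), with cad (214), Hnf4 (145) and an intergenic peak shared by GATAe and srp (107). That shared peak was absent from the thresholded list of replicate 1 but present in its ranked list. Of the members without, fkh and byn had no pooled peak, and fkh had 2 summits in replicate 2. Tracheal genes had 7 of 11 (63.6% against 66.2% ± 14.3, adjusted permutation p = 1), with btl, the tracheal FGF receptor gene (391), pyd (245), apt (163) and verm (149), and without kni and knrl. Within 1 kb of a TSS, muscle had 2 of 14 (14.3% against 43.1%, adjusted permutation p = 0.0626). Gut and fat body had 1 of 10 there (10% against 44.2%, adjusted permutation p = 0.0798). Glia (33.3% against 44.8%) and trachea (27.3% against 44.3%) differed less. A shortfall of peaks is thus not shown to be particular to the neuronal lists. Of the tissue-list members named here with a peak, only loco, Mef2 and apt had their strongest peak closest to their own TSS. Across all lists, 58 of the members taken by the naming rule had a peak, and that peak was closest to the member's own TSS in 18 and to another gene's in 40. Of 13968 protein-coding genes, 7982 had a summit in the gene or within 5 kb and 5015 one within 1 kb of a TSS.

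**Figure D3:**
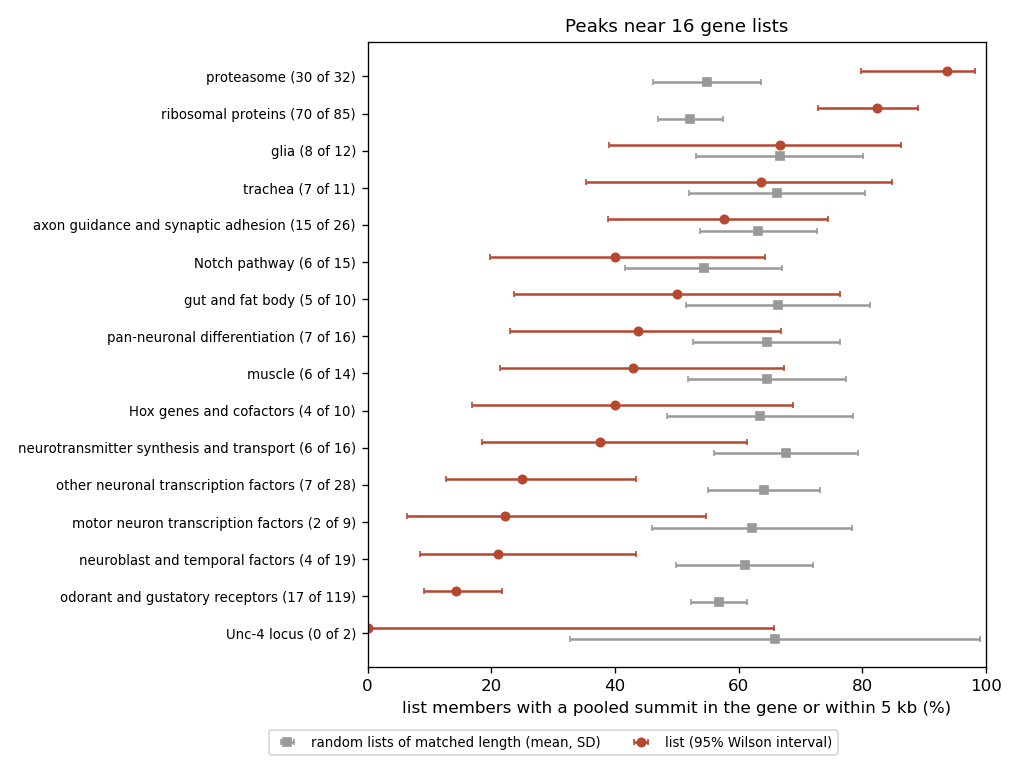
Share of members with a pooled summit in the gene or within 5 kb (x axis, %) for each of the 16 gene lists (y axis), as red points with 95% Wilson intervals, beside the mean and SD of random lists of matched length in grey. Proteasome (93.8%) and ribosomal protein genes (82.4%) lie above their random lists, and receptor genes (14.3%) below theirs.

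Summits were rich in TATCGA and related sequences. TATCGA lay within 50 bp of the summit in 32.1% (30.8 to 33.4) of pooled peaks and in 3.47% of flanks 500 bp away, with 41.7% against 3.62% in replicate 1 and 42.7% against 3.07% in replicate 2. ATCGAT (28.0% against 3.29%), CGATAG (24.5% against 2.14%), CGATAA (19.4% against 4.37%) and ATATCG (17.8% against 3.65%) came next by excess, followed by AATCGA (18.2% against 6.82%), ACTATC (13.4% against 2.39%), AAAATA (27.0% against 17.9%), CGATAC (10.6% against 2.33%) and CCGATA (10.9% against 2.69%). Of these 10 six-mers, 6 hold CGATA, a sequence known to be bound by the insulator protein BEAF-32. The palindrome TATCGATA, the site of the promoter factor DREF, lay at 13.6% (12.6 to 14.5) of summits and 0.245% of flanks (p = 5.01e-181, two-sided exact McNemar test), a sequence chosen after the six-mers had been seen. In all, 340 of 2080 six-mers were more frequent at summits and 587 less frequent after adjustment over all of them (two-sided exact McNemar tests), and each of the 10 named passed in both replicates, the weakest being AAAATA (8.68 percentage points, adjusted p = 1.77e-14 in replicate 2). Most summits lay close to a TSS, so these tests also compare promoter sequence with sequence 500 bp away. Promoters without a peak were not counted, so the excess is not shown to be particular to promoters with peaks. At the fewer peaks more than 1 kb from a TSS, 38 six-mers were higher and 10 lower. Among the 373 peaks more than 1 kb from a TSS, the excess of TATCGA was 5.36 percentage points and did not pass (adjusted exact p = 0.203), the only alternative in which it did not. There ATCGAT, CGATAA and ATATCG still passed (7.51, 6.97 and 6.70 percentage points; adjusted exact p = 0.0157, 0.0356 and 0.00974), whereas CGATAG, AATCGA, ACTATC, CGATAC and CCGATA did not (adjusted exact p from 0.386 to 1) and AAAATA changed direction (-6.43, adjusted p = 0.339).

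**Figure D4:**
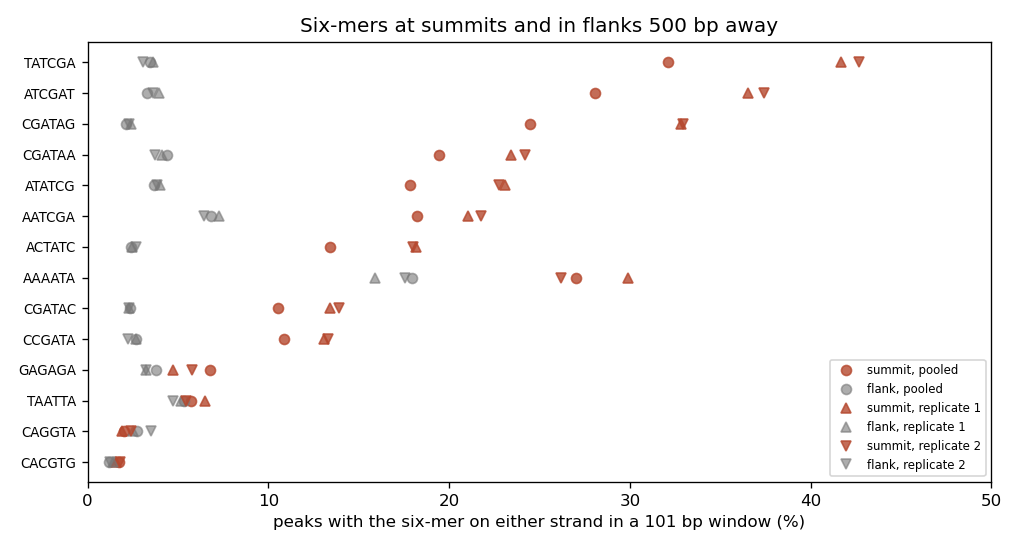
Share of peaks with each six-mer on either strand (x axis, %) in the window at the summit (red) and in the flank (grey), for the pooled list and each replicate. TATCGA stands at 32.1% of pooled summits and 3.47% of flanks, whereas TAATTA differs by less than 1 percentage point in the pooled list.

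Over the pooled list as a whole, the homeodomain core TAATTA, named in advance, was not detectably more frequent at summits than beside them. It lay at 5.74% (5.12 to 6.42) of pooled summits and 5.33% (4.73 to 5.99) of flanks, an excess of 0.408 percentage points that did not pass (adjusted p = 0.405, two-sided exact McNemar test over 5 sequences). The paired site TAATNNNATTA lay at 0.612% against 0.449% (adjusted exact p = 0.405). GAGAGA was more frequent at summits, 6.80% against 3.78% (adjusted exact p = 4.5e-11), and the excess was 13.9 percentage points at the 373 peaks more than 1 kb from a TSS (adjusted p = 2.63e-08). Among the 479 nuclear ones of the 500 peaks of highest signal it turned to -1.04 percentage points (adjusted exact p = 0.764). CACGTG, an E-box, was slightly more frequent over all peaks (1.76% against 1.18%, adjusted exact p = 0.0477) and at distal peaks (2.68, adjusted p = 0.0323), but turned to -1.04 in those 479. CAGGTA, the core of sites for the early activator Zelda, was slightly less frequent (2.02% against 2.71%, adjusted exact p = 0.0477). In the conservative list neither CAGGTA (-0.469) nor CACGTG (0.291) passed (adjusted exact p = 0.322 for both). In replicate 1 alone TAATTA passed, with an excess of 1.36 percentage points (adjusted exact p = 0.0481), CAGGTA did not (-0.607, adjusted p = 0.161) and CACGTG did not (0.145, adjusted p = 0.694), while GAGAGA passed with a smaller excess (1.504, adjusted p = 0.00694). In replicate 2 alone TAATNNNATTA (0.507, adjusted exact p = 0.0203) and CAGGTA (-1.11, adjusted p = 0.0227) passed and CACGTG did not (0.541, adjusted p = 0.142). CAGGTA also passed with a window of 100 bp either side of the summit (-1.43, adjusted exact p = 0.00295) and with flanks 1000 bp away (-1.10, adjusted p = 0.00174), but not at distal peaks (0.804, adjusted p = 0.686) or in those 479 (a difference of 0). TAATTA also passed with a window of 100 bp either side of the summit (1.69 percentage points, adjusted exact p = 0.014) and with flanks 1000 bp away (0.959, adjusted p = 0.0458). Among those 479 its excess was 2.51 percentage points and did not pass (adjusted exact p = 0.764). Over all its alternatives adjusted p ranged from 0.014 to 0.764. Its share changed with rank in the pooled ranked list, which was not tested. It lay at 7.8% of summits against 4% of flanks in ranks 1 to 500, and at 3.86% against 6.44% in ranks 5001 to 10000. The value over all pooled peaks does not show such a change.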

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

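The tests of homeodomain-led binding, of general promoter enrichment, of mitochondrial copy number and of spacing on the X were chosen after the result was seen, while the test of base composition was set out before its result was seen. With 1 group in the series, no biological explanation was tested against another.

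Signal outside the main measurement was present on the mitochondrial genome, where the pooled list held 22 summits. The peaks covered 59.2% of that genome against 1.40% of the nuclear chromosomes, and the highest signal was 22.3 times the highest nuclear one. Such breadth is what many copies of the mitochondrial genome per cell would give, and this explanation stays open. Whether the authors' signal value corrects for copy number was not given in the sources used here, and whether reads from nuclear copies of mitochondrial sequence contribute was not tested.

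Summits below the authors' threshold were present at the Unc-4 locus, in the ranked lists, which the tests of the report do not use. Ranked summits are common: the pooled ranked list held 110 between X:17698569 and X:17884011. The median distance from a coding gene on the X to a ranked summit was 0 bp, in the pooled list and in replicate 2. No random count was computed for the windows of OdsH and unc-4. Their counts therefore do not show signal above background. Near OdsH the pooled ranked list held 7 summits, the strongest with a signal of 46.6 at rank 6045 of 46847 nuclear peaks. Near unc-4 the ranked list of replicate 2 held 3 summits, the strongest with a signal of 14.5 at rank 12683 of 45920, while the pooled ranked list held 0 and its nearest summit was 16778 bp away. Chance spacing of ranked summits could leave a gene that far out: 4.69% of 2196 coding genes on the X (103) were as far from a pooled ranked summit. For other lists the share was taken at the distance of unc-4 from that list's own nearest summit. It was 4.37% for the conservative ranked list (17843 bp) and 6.10% for that of replicate 1 (17893 bp). For pooled thresholded summits it was 17.9% (394 genes, 25829 bp). Chance and a true lack of signal at unc-4 cannot be told apart, because the pooled ranked share, on which the test was set, falls between its bounds of 5% and 1% and the other lists fall on either side of 5%.

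TATCGA lay at 32.1% of summits, although Unc-4 is a homeodomain protein. Base composition of the windows is argued against: in 20 shuffles that kept the dinucleotides of each window the share of TATCGA was at most 5.78%. In the 500 strongest nuclear peaks the excess of TAATTA was 2.40 percentage points with an upper 95% bound of 5.48, and that of TATCGA was 60.6. TAATTA was thus not the leading sequence there. The test was chosen after these values had been seen and asks only about a leading role. It cannot exclude binding through TAATTA at a minority of peaks. General enrichment of active promoters in the libraries stays open, since promoters of proteasome genes held peaks 82.7 percentage points more often than those of odorant and gustatory receptor genes. The same values could follow from recruitment of Unc-4 to such promoters by other proteins, and no control library was analysed here to separate these accounts.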

How the results depend on the processing

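The alternative of the 500 nuclear peaks of highest signal was chosen after the data had been seen, and every other alternative was fixed earlier. Over 146 results, 647 alternative values were computed: 495 were the same (direction and side of the threshold kept, or, without a test, within counting error or, for counts, 1.5 times the main count), 38 kept their direction but no longer passed, 8 kept it and newly passed, 87 values without a test moved further and 19 changed direction. A difference of exactly 0, as for CAGGTA in the 500 strongest peaks, has no direction and was counted as keeping it. Promoter share, signal by location and the lists of ribosomal proteins and of odorant and gustatory receptors kept direction and call in every alternative tried for them. Values below are percentage points against random lists or flanks unless said otherwise, and the cause was not tested, except that the 500 strongest peaks and the 373 distal peaks give fewer peaks to test. With the 500 peaks of highest signal, of which 21 are mitochondrial and 479 were tested, and with the 500 nuclear ones, the X ratio became 0.977 and 0.968, motor neuron factors -13.2 and -13.8, other neuronal factors -13.5 and -14.1, neuroblast factors -13.2 and -13.8, neurotransmitter genes -14.4 and -15.1, proteasome 9.69 and 9.32, GAGAGA -1.04 and -1, CACGTG -1.04 and -1; lists above random numbered 1 and 1, lists below 1 and 1, six-mers higher 162 and 171, six-mers lower 258 and 281. With the gene of the nearest TSS, values were -22.7 for motor neuron, -18.8 for other neuronal and -16.2 for neuroblast factors, -25.6 for neurotransmitter genes, 4.93 for axon guidance and -2.98 for glia, and 1 list lay below. With Fisher's exact test without matching, they were -34.9 for motor neuron factors and -19.7 for neurotransmitter genes, neither of which passed, 0.548 for axon guidance and 6.497 for trachea, and 3 lists lay below. With promoter windows, neuroblast factors stood at -23.6 and did not pass, pan-neuronal genes passed at -29.6, and glia stood at -11.4 and did not pass. With the conservative list, pan-neuronal genes passed at -30.4, while CAGGTA (-0.469) and CACGTG (0.291) did not pass. For distal peaks, TAATTA was at -2.41, TAATNNNATTA at -0.268, CAGGTA at 0.804 and AAAATA at -6.43, while GAGAGA (13.9) and CACGTG (2.68) passed, with 38 six-mers higher and 10 lower. TAATTA passed at 1.69 with 100 bp windows and at 0.959 with flanks 1000 bp away. The overlap of replicate 1 was 55.8% with reciprocal overlap, 64.5% by summits within 100 bp and 79.9% among the 500 strongest peaks. With 1 replicate left out in turn, values ranged from 1.02 to 1.14 for the X ratio, from -38.3 to -30.2 for motor neuron and from -36.4 to -28.0 for neuroblast factors, from -29.2 to -26.6 for pan-neuronal genes, from -2.95 to 14.6 for axon guidance, from -8.01 to -4.04 for glia, from -27.3 to 6.45 for gut and fat body, from 0.709 to 1.36 for TAATTA, from 1.504 to 2.57 for GAGAGA, and from 3 to 5 for lists below. Of 100 genes taken by the naming rule, 3 gained or lost all their summits in the conservative list, 5 without replicate 1 and 6 without replicate 2. Unknown read depth limits what the absence of a peak means.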

Other observations

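The test of GAGAGA against TATCGA was chosen after the result was seen, as were the gene families and the test that counts each head-to-head pair once, while the tests on families and on head-to-head genes were set out before their results were seen.

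Further gene families differed in how often they held peaks. Mitochondrial ribosomal proteins had a summit in the gene or within 5 kb in 64 of 73 genes (87.7% against 44.4% ± 5.65 SD in random lists of matched length, adjusted permutation p = 0.000175), subunits of the NADH dehydrogenase complex in 28 of 40 (70.0% against 50.7% ± 7.74, adjusted p = 0.0187) and aminoacyl-tRNA synthetases in 27 of 32 (84.4% against 63.6% ± 8.53, adjusted p = 0.0187). Translation initiation factors had one in 31 of 44 (70.5% against 59.8% ± 7.26), which did not pass (adjusted permutation p = 0.157). Cytochrome P450 genes had 26 of 83 (31.3% against 62.5% ± 5.21), cuticular protein genes 9 of 70 (12.9% against 49.8% ± 5.73) and ionotropic receptor genes 19 of 60 (31.7% against 61.8% ± 6.20), each with an adjusted p of 0.000175 (two-sided). Counting only summits within 1 kb of a TSS, initiation factors passed (54.5% against 37.6%, adjusted permutation p = 0.0332) and tRNA synthetases did not (18 of 32, 56.2% against 42.2%, adjusted permutation p = 0.152). The hypothesis that peaks favour families of basic cell function in general needed all 4 of these families above random lists, and 3 were, so it stays open as a whole.

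Promoters shared by gene pairs held peaks more often than single ones. Of 3815 coding genes in head-to-head pairs, with TSSs of opposite strand within 500 bp, 66.2% (64.7 to 67.7) had a promoter peak, against 24.5% (23.7 to 25.4) of 10153 other genes, but 1 summit can count for both genes of a pair, so this comparison decides nothing. With each of 1850 pairs counted once, in a window of 500 bp either side of the midpoint, 63.7% (61.5 to 65.8) held a summit. Within 500 bp of the outermost TSS of the 10153 other genes the share was 20.1% (19.3 to 20.8), and either of 2 such promoters would hold one in 36.1%. The share of pairs was above both, in line with the hypothesis that peaks favour shared promoters; gene function and activity were not matched.

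GAGAGA and TATCGA tended to mark separate promoter peaks. GAGAGA lay at 26 of 1535 promoter peaks with TATCGA (1.69%) and at 237 of 2991 without it (7.92%), an odds ratio of 0.200 (p = 2.32e-20, two-sided Fisher's exact test). The median signal was 254 with TATCGA, 85.4 without it and 78.4 with GAGAGA. This is consistent with different promoter classes entering the peak list, a hypothesis found and tested on the same peaks.

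Down the pooled ranked list the sequence and place of peaks changed. The share of promoter summits was 99.6% in ranks 1 to 500 and 30.1% in ranks 20001 to 46847, and that of TATCGA 63.8% and 3.26%. GAGAGA was at 2.40% of summits against 4.40% of flanks in ranks 1 to 500, 10.6% against 3.27% in ranks 2001 to 5000 and 3.69% against 3.53% in ranks 20001 to 46847. TAATTA was at 7.80% of summits against 4% of flanks in ranks 1 to 500, 6.60% against 3.80% in ranks 501 to 1000, 6.5% against 4.40% in the ranks from there to 2000, 5.03% against 5.60% in ranks 2001 to 5000 and 3.86% against 6.44% in ranks 5001 to 10000. In the 500 strongest nuclear peaks of the thresholded list, where the peaks and the sides of their flanks differed in part, it was at 7.60% against 5.20%. These shares were not tested.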
